A study of Lacticaseibacillus rhamnosus GG with 9 samples.

How the data were processed

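The series holds 9 RNA-seq libraries of Lacticaseibacillus rhamnosus GG, a probiotic lactic acid bacterium. The labels place 3 libraries at pH 4 for 1 h, 3 at pH 4 for 24 h and 3 at pH 7. The labels of the pH 7 libraries carry the letters CCG, which they do not explain, and no time. Per the labels' protocols, libraries were made from total RNA with an Illumina TruSeq RNA kit. Bowtie, DESeq and edgeR are named in the submitters' processing notes, without a role or a version. The genome build, the annotation, the counting program and its strand setting are not given in the sources used here.

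The authors deposited 2 tables, each with 2838 genes listed by locus tag and 3 columns of values, 1 per group. Per the file headers, the first table holds the raw read count per gene and the second the RPKM, both as averages of a group. RPKM is by definition a read count scaled to gene length and library size. Which library size was used is not given in the sources used here. Every deposited value is a whole number, so both averages were rounded, and the RPKM column was therefore handled as a score rather than as exact RPKM. Values per library were not used here, because both tables hold averages alone. The authors' averages therefore carry no SD and no number of replicates, and how the libraries of a group were averaged is not given in the sources used here. All 6 value columns belong to a group of the labels.

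The design fixed before the data were examined was a count test across all 9 libraries with gene lists defined by gene symbol or product. Neither part could be carried out. A count test needs values per library. None of the 2838 locus tags matched an identifier in the gene name table at hand (2830 genes, assembly ASM2847508v1). The tags could therefore not be paired with gene names here, and the 31 gene lists were applied to 0 genes. Genes are therefore reported by locus tag, and gene functions are not reported here. No genome was used, so positions on a chromosome are not given. The number inside the locus tag was taken as the order of genes along the genome, which was not checked against an annotation. The tables skip 106 of the tag numbers up to 2944.

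The main measure was the log2 ratio of average RPKM between 2 groups after adding a pseudocount of 1. The pseudocount understates the change of genes with low values. Folds of named genes, unless given in CPM, are plain ratios of average RPKM without the pseudocount. Genes with an average raw count of at least 10 in at least 1 group were kept, which left 2819 genes and removed 19. A gene is called higher or lower when the ratio is at least 2-fold, and the number at 4-fold is given beside it. This is a rule of size. No p-value is given, because without values per library the difference between 2 averages has no replicate check. Up to 2 genes per direction and comparison are named: the largest log2 ratios among kept genes with a log2 mean CPM of at least 4 over the groups, CPM being the average raw count scaled to an equal total in each column, and an RPKM above 0 in both groups. The rule fixed beforehand asked for 6, a test and a gene description as well. It was shortened because no tag matched the gene name table at hand.

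The range that rounding alone allows was computed for the RPKM ratio of each named gene, without the pseudocount. A counting interval was computed from the average raw counts by the exact (Clopper-Pearson) binomial method at 95%, each average being taken as the count of 1 library. It is wider than the counting error of an average over several libraries. Shares of reads carry a 95% Wilson interval on the same basis. Intervals cover counting error only, and not the spread between cultures or libraries. The columns of average raw counts add up to 774376 reads at pH 4 for 1 h, 1670016 at pH 4 for 24 h and 1690218 at pH 7. Library totals behind these averages are not known.

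Blocks are runs of at least 4 consecutive locus tag numbers that all pass the 2-fold rule in 1 direction. They were compared with 100 shuffled gene orders. The definition of a block was chosen after the data were seen. The comparisons at 1 h and 24 h share the pH 7 columns, so their overlap was set beside 100 simulated draws in which both pH 4 groups had the pH 7 profile and carried counting error alone. The spread between libraries is not in that simulation. The pH 7 libraries could not be split. The 2 tables were also compared with each other through the ratio of average raw count to average RPKM, for genes with at least 100 reads and an RPKM of at least 50 in every group.

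The procedure was tested on simulated data made from the real columns with 200 genes changed. For pH 4 for 24 h against pH 7, with 2608 genes kept, 47 of 48 genes raised by 1.5 on the log2 scale and 50 of 50 raised by 3 were called, and 1 of 2413 unchanged genes passed. For pH 4 for 1 h against pH 7, with 2588 genes kept, 45 of 45 and 48 of 48 were called at those sizes and 19 of 2401 unchanged genes passed. The simulated libraries of a group shared 1 profile and carried counting error alone. These numbers are therefore not error rates for real libraries, whose spread is not in the simulation. The alternatives were a pseudocount of 0.1, no filter, a minimum of 50 reads, the count table as CPM with and without centring on the median gene, RPKM rescaled to equal column totals or by median-of-ratios factors, and the removal of 2 sets of genes. Leaving out a replicate, other tests and a replicate block need values per library and were not run. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.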

Results

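RNA from L. rhamnosus GG kept at pH 4 for 1 h, at pH 4 for 24 h or at pH 7 was sequenced to find genes whose expression differs between acidic and neutral conditions. Each group has 3 libraries in the labels, and the deposited tables give 1 average per gene and group. The average raw counts add up to 774376 reads at 1 h, 1670016 at 24 h and 1690218 at pH 7. The median gene had an average raw count of 86 at 1 h, 183 at 24 h and 140 at pH 7, and an average RPKM of 143, 149 and 140. The 100 most abundant genes of each group took 46.4% of its reads at 1 h, 47.1% at 24 h and 47.0% at pH 7. Below, higher and lower mean a difference of at least 2-fold between group averages. The averages have no replicate check, so none of these differences has been set against the spread between libraries.

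The first comparison asked which genes differed after 1 h of acid. At 1 h of pH 4, 467 of 2819 genes were higher than at pH 7 and 237 were lower, while 2115 (75.0%) differed by less than 2-fold. At 4-fold the numbers were 103 higher and 60 lower. LGG_01121 had an average RPKM of 5 at pH 7 and 122 at 1 h, a log2 ratio of 4.36. LGG_01102 also had 5 at pH 7 and reached 106 at 1 h, a log2 ratio of 4.16. Both were low at pH 7, with average raw counts of 10 and 2, and the counting intervals of their ratios, taken from the average raw counts scaled to equal column totals (CPM), ran from 18.5 to 74.2 and from 5.90 to 210.6. In the other direction LGG_02639, one of the more abundant genes at pH 7 with an RPKM of 37556, was at 2434 at 1 h, 15.4-fold lower. Its fold in CPM was 9.64, with a counting interval of 8.93 to 10.4. LGG_00644 went from 1348 at pH 7 to 89 at 1 h, 15.1-fold lower, or 22.2-fold in CPM with an interval of 16.1 to 31.5. Of the 467 higher genes, 8 were listed at an RPKM of 0 at pH 7.

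Part of the genes that differed at 1 h lay next to each other. Of the 467 higher genes, 151 (32.3%) fell into 23 blocks of consecutive locus tags, and of the 237 lower genes 82 (34.6%) fell into 15 blocks. In 100 shuffled orders at most 22 higher and 11 lower genes did so. The longest block of higher genes had 46 members, including LGG_01121 and LGG_01102. The log2 ratios of adjacent genes correlated at r = 0.57 across genes, against a highest value of 0.04 in shuffled orders. Genes are not independent replicates, and shuffling removes any link between neighbours. Here and below, exceeding the shuffled orders shows that neighbours differed together. It does not set the blocks apart from a difference between libraries.

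The split between higher and lower genes at 1 h depended on the scaling. In the RPKM table the median log2 ratio was 0.03 and 66.3% of the differing genes were higher. In the count table, expressed as CPM, the median gene was shifted by 0.42 and 80.2% were higher (837 against 207). After centring on that median 56.5% were higher, 520 against 401. In both tables, the count table being centred, 433 genes were higher and 220 lower.

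The second comparison asked which genes differed after 24 h of acid. At 24 h of pH 4, 666 genes were higher than at pH 7 and 397 were lower, with 1756 (62.3%) within 2-fold. At 4-fold, 294 genes were higher and 53 lower. LGG_01099 had an average RPKM of 8 at pH 7, 114 at 1 h and 1826 at 24 h, a log2 ratio of 7.67 at 24 h. LGG_01110 had 39, 476 and 6608 in the same order, a log2 ratio of 7.37. Without the pseudocount the RPKM ratio of LGG_01099 was 228, and rounding alone lets it lie between 214.8 and 243.5. Its ratio in CPM was 292.3, with a counting interval of 153.7 to 639.9. For that interval the average raw count of 9 at pH 7 was taken as that of 1 library. LGG_02639 was the gene furthest below its pH 7 value among those eligible, at an RPKM of 1815, 20.7-fold lower. In CPM the fold of LGG_02639 was 16.8, with a counting interval of 15.6 to 18.0, so the 2 tables differed by more than counting error. LGG_01814 went from 122 at pH 7 to 7 at 24 h, 17.4-fold lower, or 13.6-fold in CPM with a counting interval of 8.44 to 23.4.

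**Figure D1:**
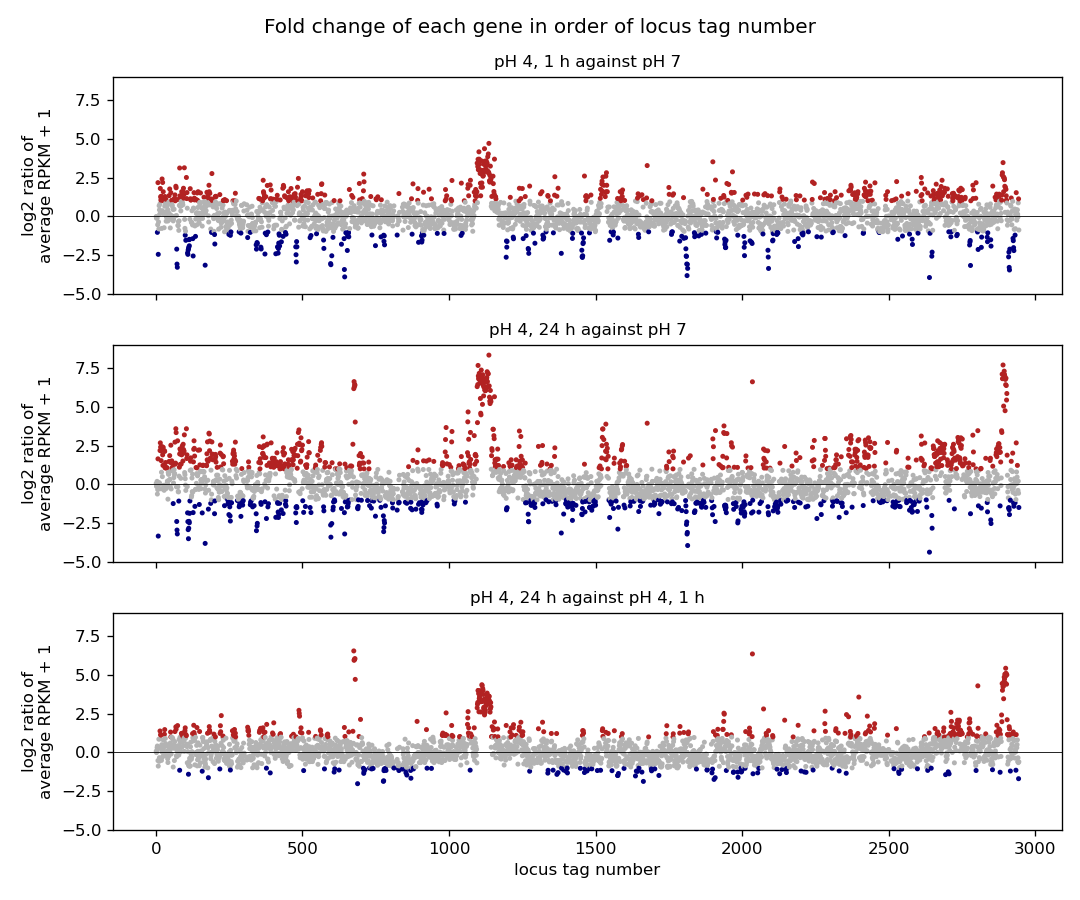
Log2 ratio of average RPKM + 1 (y axis) for each kept gene, in order of locus tag number (x axis), for the 3 comparisons; red points are at least 2-fold higher, blue points at least 2-fold lower, and each point is a ratio of 2 group averages with no error. The densest red group, in the middle panel, holds the block of 48 genes that were higher at 24 h.

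Of the 666 genes higher at 24 h, 327 lay in 45 blocks of consecutive tags, against at most 60 genes in shuffled orders. Of the 397 lower genes, 101 lay in 19 blocks, against at most 12. The 3 blocks with the highest median ratios had 48, 15 and 6 genes. A further block of 4 genes, 1 tag away from the block of 15, had a median log2 ratio of 5.13, and the next block had 2.76. The longest, with 48 genes including LGG_01099 and LGG_01110, had a median RPKM of 11.5 at pH 7, 112 at 1 h and 945 at 24 h. Its share of all reads was 0.0404% at pH 7 (95% interval 0.0375 to 0.0436), 0.505% at 1 h (0.489 to 0.521) and 4.30% at 24 h (4.27 to 4.33). A block of 15 genes had median RPKM values of 29 at pH 7, 93 at 1 h and 2131 at 24 h, and took 0.0460%, 0.187% and 4.57% of reads. A block of 6 genes, which includes LGG_00675, had median values of 235, 170 and 13747.5 and took 0.106%, 0.102% and 8.00% of reads. All 3 blocks together took 0.192% of reads at pH 7, 0.793% at 1 h and 16.9% at 24 h. Median log2 ratios at 24 h were 6.47, 6.77 and 6.34 from RPKM, and 6.37, 6.78 and 6.20 from the centred count table.

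The blocks also differed in timing. At 1 h, 47 of the 48 genes in the longest block and 12 of the 15 in the second were already higher than at pH 7, with median log2 ratios of 3.01 and 1.74. None of the 6 genes in the third block was higher at 1 h: their log2 ratios ran from -0.69 to 0.68. Among blocks that were lower at 24 h, the block of 8 genes that includes LGG_01814 had a median RPKM of 102.5 at pH 7, 11.5 at 1 h and 17 at 24 h. All 8 were lower at both times. A block of 9 genes had median values of 970, 250 and 167, with 8 genes lower at 1 h and 9 at 24 h. A block of 5 genes had 1015, 295 and 180, with 4 genes lower at 1 h and 5 at 24 h. At 24 h over 1 h the median log2 ratio of the block of 9 was -0.74 from RPKM and 0.03 from the centred count table. For the block of 5 it was -1.17 and -0.65, and for the block of 8 it was 0.48 and 0.53. A further fall of the block of 9 after 1 h was therefore seen in the RPKM table alone.

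**Figure D2:**
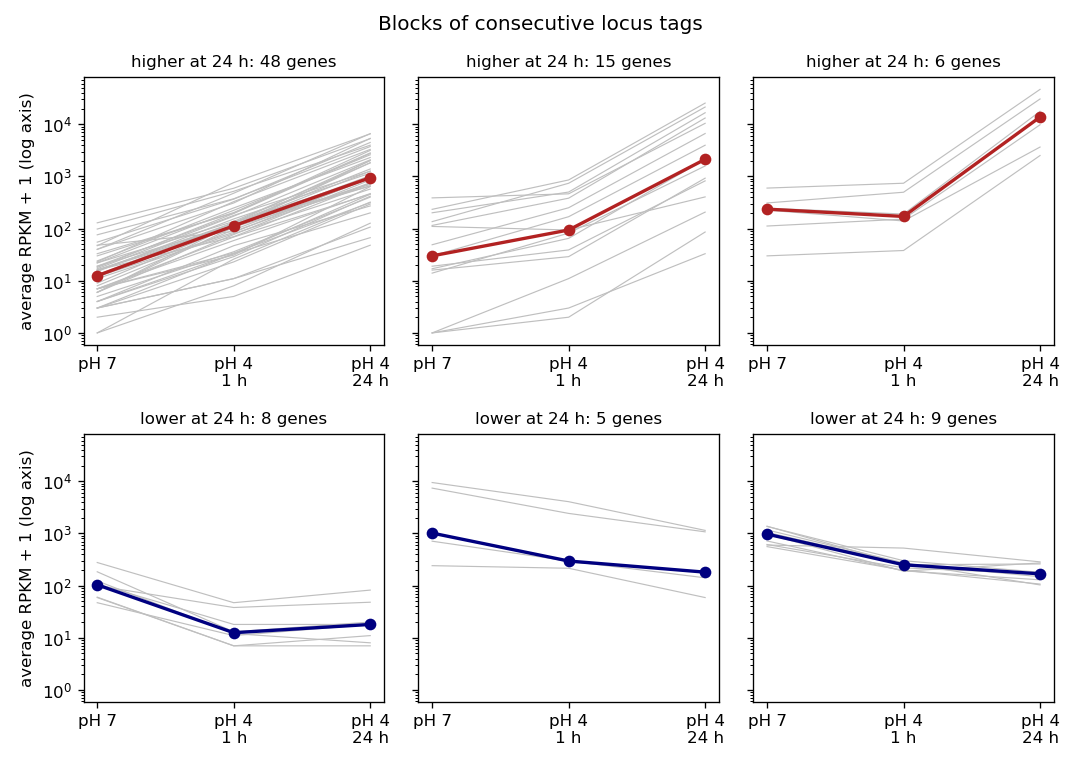
Average RPKM + 1 on a log axis (y axis) at pH 7, pH 4 for 1 h and pH 4 for 24 h (x axis) for the 3 blocks of consecutive locus tags with the highest and the 3 with the lowest median ratio at 24 h; grey lines are single genes and the coloured line is the median of the block. The block of 48 genes is already raised at 1 h, from a median RPKM of 11.5 to 112, while the block of 6 genes goes from 235 to 170 before reaching 13747.5 at 24 h.

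At 24 h the RPKM table had a median log2 ratio of -0.0041 and 62.7% of differing genes were higher. Without centring, the count table was shifted by 0.28 and 78.7% were higher (842 against 228), and with centring 62.9% were higher (664 against 392). Rescaling RPKM to equal column totals gave 74.0% (776 against 272). The labels give no time for pH 7, so acid and time in culture are not separated in this comparison.

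Most genes that were higher at 1 h were higher at 24 h too. Of the 467 genes higher at 1 h, 381 (81.6%) were also higher at 24 h, and of the 237 lower at 1 h, 165 (69.6%) were also lower at 24 h. Independent lists of these sizes would share 110.3 and 33.4 genes. The simulated groups without any change shared at most 14 higher and 10 lower genes. Of the 2819 genes, 0 were higher at 1 h and lower at 24 h, and 2 were lower at 1 h and higher at 24 h. Across genes the log2 ratios of the 2 comparisons correlated at r = 0.81, with a covariance of 1.22. Unchanged groups sharing the pH 7 columns gave a median r of 0.38 and a median covariance of 0.04, a difference in covariance of 1.18. The simulation holds counting error alone, so part of the excess may come from the shared pH 7 libraries.

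**Figure D3:**
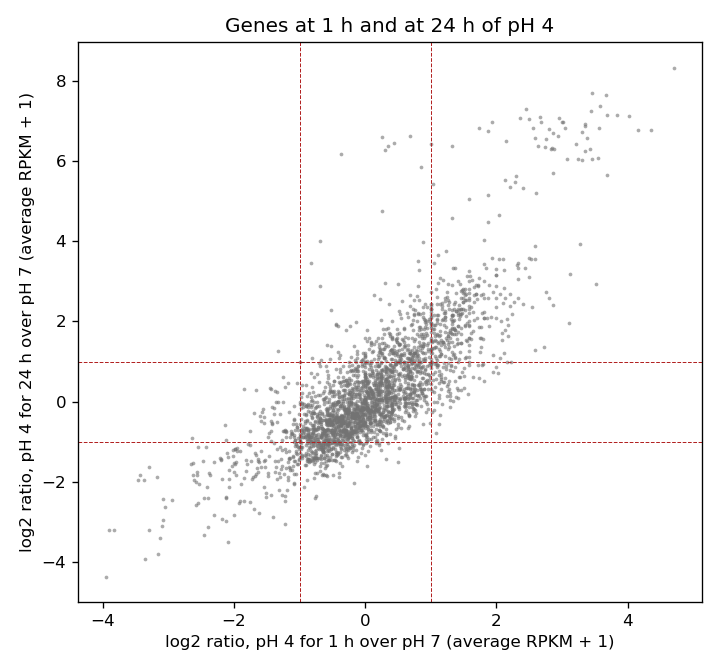
Log2 ratio to pH 7 at 1 h (x axis) against that at 24 h (y axis), from average RPKM + 1, with 1 point per kept gene and dashed lines at 2-fold. The upper right corner beyond the lines holds 381 genes and the lower left corner 165.

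The third comparison set the 2 times at pH 4 against each other, and it does not involve the pH 7 columns. At 24 h, 365 genes were higher than at 1 h and 124 were lower, while 2330 (82.7%) were within 2-fold. At 4-fold, 98 were higher and 1 was lower. LGG_00675 had an RPKM of 189 at 1 h and 17711 at 24 h, 93.7-fold higher, with a counting interval in CPM of 99.6 to 122.7 around a ratio of 110.4. LGG_02035 went from 1548 to 126211, 81.5-fold higher, and had the highest RPKM of any gene at 24 h. At pH 7 these genes stood at 245 and 1290. LGG_00688 was at 1543 at 1 h and 381 at 24 h, 4.05-fold lower, and at 1089 at pH 7. LGG_01663 was at 901 at 1 h and 246 at 24 h, 3.66-fold lower, and at 427 at pH 7.

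Genes with a further change between the times were mostly higher ones. Among the 381 genes higher at both times, 154 were again at least 2-fold higher at 24 h than at 1 h. Of the 285 genes higher at 24 h but below the 2-fold rule at 1 h, 141 were at least 2-fold higher at 24 h than at 1 h, and the other genes differed by less between the times. Of the 467 genes higher at 1 h, 33 were at least 2-fold lower at 24 h than at 1 h. Of the 237 genes lower at 1 h, 40 were at least 2-fold higher at 24 h than at 1 h. Of the 165 genes lower at both times, 8 were at least 2-fold lower again at 24 h. Among the 365 genes higher at 24 h than at 1 h, 123 lay in 13 blocks of consecutive tags, against at most 13 genes in shuffled orders. Of the 124 lower genes 8 did, against at most 4. The share of differing genes that were higher was 74.6% from RPKM, 61.7% from the centred count table (297 against 184), 60.2% from CPM (292 against 193) and 62.7% with equal column totals (299 against 178).

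The 2 tables gave different pictures of the 1 h group for some genes. Where the libraries of each group share 1 profile, the average raw count divided by the average RPKM differs between groups by 1 factor for all genes. Had RPKM been scaled to the column totals, that factor would follow these totals. At 24 h over pH 7 the totals were close, 1670016 and 1690218 reads, but the median log2 ratio was 0.27. Another scaling may therefore underlie part of the shift between the 2 tables, which was not tested. Over 1188 well-covered genes, the log2 of this ratio at 24 h over pH 7 had an SD across genes of 0.099, where simulated libraries of 1 shared profile gave 0.032 over their own 1510 well-covered genes. At 1 h over pH 7 the SD was 0.34 and at 24 h over 1 h it was 0.28. Rounding can move a value by at most 0.04. The departure of a gene at 1 h was its log2 ratio minus the mean of those at 24 h and pH 7. It was centred on the median gene. By this measure 91 of the 1188 genes (7.66%) departed by more than 0.5 on the log2 scale, 84 of them downward. The longest block of strong downward departures, by at least 1, had 13 consecutive tags. Its median log2 ratio at 1 h against pH 7 was -0.87 from RPKM and -2.38 from the centred count table, against -1.43 and -1.52 at 24 h. Without the 91 departing genes, 461 genes were higher and 213 lower at 1 h. The 1188 genes include only 51 of the 666 genes higher at 24 h, and 265 of the 397 lower ones. Departures of most higher genes were therefore not measured.

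**Figure D4:**
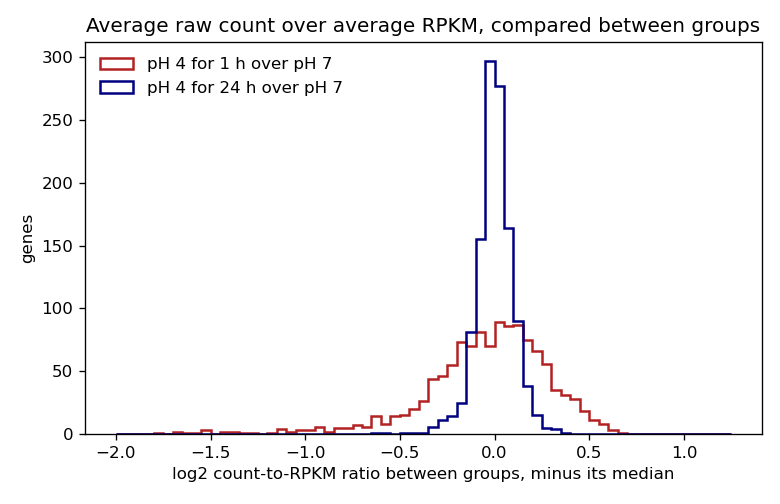
Number of genes (y axis) by the log2 ratio of average raw count to average RPKM in 1 group over another, minus its median (x axis), for 1188 well-covered genes; the red line is pH 4 for 1 h over pH 7 and the blue line pH 4 for 24 h over pH 7. The 1 h distribution is wider (SD 0.34 against 0.099) and has a tail to the left.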

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

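The tests in this part were chosen after the results were seen. The ratio of average raw count to average RPKM was looked at because the main comparisons use the RPKM table alone. Its log2 value at 1 h over pH 7 had an SD of 0.34 across 1188 genes. At 24 h over pH 7 the SD was smaller, 0.099, and values of adjacent locus tags correlated there at r = 0.47. A spread shared by neighbours was therefore not seen in the 1 h group alone. Simulated libraries that share 1 profile gave 0.032, over a different set of 1510 genes and with assumed depths. If libraries of 1 group differ in depth and in expression, the ratio of a gene is pulled toward the depth of the libraries that express it most. The ratio spanned 5.46-fold across genes for 1 h over pH 7, 4.30-fold for 24 h over 1 h and 1.98-fold for 24 h over pH 7, and 3.63-, 2.80- and 1.45-fold between the 1st and 99th percentiles.

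Rounding and counting error would strike genes independently of their neighbours, whereas the departures at 1 h correlated at r = 0.63 between adjacent locus tags, against a highest value of 0.10 in 100 shuffled orders. This argues against such error as the main source. A candidate explanation is that the 1 h libraries differed in depth and in expression, with the deeper ones changed further in the direction seen at 24 h. The departure correlated across genes with the 24 h against pH 7 log2 ratio at a Spearman rho of 0.38 from RPKM and 0.44 from the count table. Without the 91 departing genes rho was 0.34 and 0.39. The correlation gives a direction and not nearness to the 24 h values. In the block of 13 tags the centred count table gave -2.38 at 1 h against pH 7, beyond the -1.52 at 24 h. From RPKM the block had -0.87 and -1.43. The link holds on balance and not for each gene. LGG_02035 and LGG_00675, far higher at 24 h, had log2 count-to-RPKM ratios at 1 h over pH 7 of -1.26 and -1.05, below the median of -0.77. LGG_02639, far lower at 24 h, had -0.45, above it. The correlation covers only 51 of the 666 genes higher at 24 h and 265 of the 397 lower ones, so it says little about the higher genes. Whether the difference lies in the cultures or in library preparation was not tested, since values per library were not used here.

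The 3 blocks with the highest median ratios at 24 h against pH 7 hold 69 genes. The tables argue against scaling as the source by size alone. The settings tried left the median gene at 24 h within 0.28 of 0 on the log2 scale, so none could have brought these ratios near 0. The median log2 ratio over all 69 genes was at least 6.36 under each scaling, pseudocount and filter tried. The lowest median of any of the blocks was 6.20, for the block of 6 genes in the centred count table. The tables also argue against counting error in the few pH 7 reads. At 24 h over 1 h, where no pH 7 value enters, the median log2 ratio of these genes was 3.61 and the lowest 2.11. How many of the 24 h libraries carried these reads stays open, and so do acid and time in culture, both untested. No biological explanation beyond the labelled condition was tested.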

How the results depend on the processing

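A pseudocount of 0.1 and no filter were planned, and all other settings were chosen after the data were seen. Each of the 12 named ratios kept its direction and stayed beyond 2-fold under every one of the 9 alternatives in which its gene was kept. This was close to assured, because these genes were picked for large ratios and the settings shifted the median gene by at most 0.42. Of those 103 values, 16 moved by more than counting error. Of the counts, 65 of the values under alternatives were within 1.5 times the main one and 9 were not. With the count table as CPM, 837 genes were higher at 1 h (467 in the main setting), 228 lower at 24 h (397), 193 lower at 24 h than at 1 h (124), and 609 higher at both times (381). Centring that table gave 401 lower at 1 h (237). Rescaling RPKM to equal column totals gave 145 lower at 1 h and 105 lower at both times (165). At 4-fold, 90 genes were higher and 28 lower at both times. The median log2 ratio to pH 7 was 0.03 at 1 h and -0.0041 at 24 h in the main setting. It was 0.42 and 0.28 with CPM and 0.34 and 0.18 with equal column totals, which shifts genes across the 2-fold line. The centred table has a median of 0, and the cause of its change was not tested; nor was that of the change between the times. No paired analysis was possible because the tables hold 1 average per group, and for the same reason no replicate was left out, no count test was run and no other splits of the libraries were tried. Ratios of genes with few reads are the least precise: 257 genes had fewer than 10 reads on average at pH 7, 188 at 1 h and 23 at 24 h, numbers that do not follow the column totals.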

Other observations

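The tests in this part were chosen after the result was seen. The direction of change went with the level of expression. Of the 705 genes in the lowest quartile by mean log2 RPKM over the groups, 371 were at least 2-fold higher at 24 h than at pH 7 and 31 lower. In the highest quartile 58 of 705 were higher and 192 lower. The median log2 ratio went from 1.05 in the lowest quartile through 0.18 and -0.29 to -0.55 in the highest. The centred count table gave 369 higher and 30 lower in the lowest quartile and 57 and 198 in the highest. At 1 h the lowest quartile had 234 higher and 36 lower, and the highest 45 and 81. The centred count table gave 242 and 42 in the lowest quartile at 1 h, and 57 and 171 in the highest. With equal column totals the highest quartile at 1 h had 80 higher and 42 lower, the opposite order.

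Genes with an average RPKM below 10 numbered 271 at pH 7, 133 at 1 h and 71 at 24 h. The SD of log2 RPKM across genes was 2.70 at pH 7, 2.34 at 1 h and 2.17 at 24 h. A uniform background added to every gene, as DNA in the libraries could give, would lift low genes most. After the 5th percentile of each group was subtracted from its RPKM values (5 at pH 7 and 16 at 24 h), 268 of the lowest-quartile genes were higher and 150 lower, against 371 and 31 before. Subtracting the 1st percentile (2 at pH 7 and 5 at 24 h) left 351 higher and 54 lower. At the larger size the number of lower genes rose too. Either the subtraction overshoots for part of them or a background had hidden decreases, and this test cannot tell which. A background of 10 RPKM or more at every gene is argued against by 22 genes whose upper counting limit at 24 h lay below 10, where counting error alone would give about 4.6. These genes cannot speak to a background that spared some genes. A smaller or uneven background stays open as a contribution to the higher values of low genes, as do a response to acid and a change with time in culture. For the highest quartile, whose median log2 ratio was -0.55, a background is argued against at fixed column totals. There, 16 RPKM at every gene would dilute the others by only -0.03 on the log2 scale. The RPKM totals differ, 1951020 at 24 h and 2241283 at pH 7, so the size of this gap depends on the scaling. With equal column totals the highest quartile at 24 h had 73 higher and 132 lower.

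Of the 100 genes with the highest RPKM at pH 7, 80 were among the 100 highest at 1 h and 70 at 24 h.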
